A study of Mus musculus with 6 samples.

How the data were processed

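Gene expression was profiled on 6 Agilent arrays with 2 colours, each comparing RNA of WT and Dnmt3a-null (KO) neural stem cells. Per the labels, 4 arrays are biological replicates of proliferating and 2 of differentiating cells, with 500 ng of total RNA per label and growth factors at 10 ng/ml in the culture medium. The labels give each channel's genotype and dye, and the groups follow them. Spot intensity values, as mean pixel signal and local median background per dye, were deposited as scanner output of Agilent Feature Extraction 9.5.1.1 (array design 014868), per the file headers. The deposited processed intensity values had been background-subtracted, detrended and dye-normalized by that program, per the file headers. Its log10 ratio is Cy5 over Cy3, per the file headers. The authors' value table holds the same log10 ratios turned to KO over WT on every array (correlation 1 or -1 with the scanner ratios, differences up to 5e-06) with column medians of 0; what centring was applied beyond the dye normalization is not given in the sources used here. The probe positions are on build mm7.

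Mean signals were corrected with limma 3.58.1 (normexp, offset 50) in R 4.3.3, with statmod 1.5.0 and data.table version 1.17.8. Loess within each array followed, with control and outlier-marked spots at weight 0; 1639 control spots per array and 859 outlier-marked gene spots were then left out, saturated spots were kept, and repeat spots of a probe were averaged. Median backgrounds were 33 to 34 in green and 41 to 41.5 in red, and 3 to 14 green and 71 to 204 red spots per array were saturated. Of 41174 probes, 22951 were named through their accession and 18223 kept the name in the file, giving 28786 gene names. For the 8526 genes with several probes, the probe with the highest mean intensity was taken; the 3 Dnmt3a probes differ in size. Genes were tested if that probe was well above background in at least 1 channel on at least 2 of the 6 arrays, which left 18062.

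Log2 KO over WT ratios of all 6 arrays were fitted with limma (lmFit, eBayes), with 1 coefficient per condition and a dye term, so that both conditions share 1 estimate of the spread (3 residual and 2.56 prior degrees of freedom). The difference of the coefficients is the difference between KO effects. Changes from proliferating to differentiating cells within WT and within KO cells came from limma's separate-channel fit after Aquantile normalization, with an intraspot correlation of 0.763, over 18050 genes. Adjusted p-values are Benjamini-Hochberg values, 2-sided, and a gene passed under 0.05. Where a probe was not well above background on any array of a group, a bound is given. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background, per channel after loess and Aquantile. It bounds the ratio of the measured means and is not a confidence limit. The fits and list tests of these comparisons, the gene lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined; the tests of explanations for sex, normalization, cell composition and replicate 4 were not.

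Gene lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation, over 22 lists: neurogenic transcription factors, neuronal differentiation and synapse genes, astroglial, oligodendroglial, and neural stem and progenitor genes, cell cycle genes, cell cycle inhibitors, DNA methylation and demethylation genes, Polycomb and H3K27 demethylase genes, imprinted, germline, Hox, and patterning genes (ventral, dorsal and caudal), interferon response genes, immediate early and stress genes, microglial, endothelial and mural, fibroblast and meningeal, ependymal and cilia, choroid plexus and sex-linked genes, and genes next to Dnmt3a. The last list, fixed before the probe positions were seen, wrongly holds Hadha, Hadhb and Drc1, whose probes lie on chromosome 5 and not on 12 with Dnmt3a, so it is not a test of the neighbourhood alone. They hold 580 distinct genes, with 424 list entries measured. No list call held with an estimated correlation after adjustment. At an unadjusted p under 0.05 it gave 3 lists in proliferating cells, 4 in differentiating cells and 2 for the difference. The estimate lay below the preset for the neuronal (0.0081), astroglial (-0.0027) and Polycomb lists (-0.030), and above it for the other called lists. Calls of the former ended too, as did that of a simulated list with independent noise. A lost call thus does not by itself show correlated genes, and this makes no preset call more certain.

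The rule for named genes took Dnmt3a, then per comparison the 12 genes with the largest rise and the 12 with the largest fall among those that passed with the same sign on every array (no sign rule for the difference), and up to 5 of smallest p where fewer passed. It further took up to 4 members of smallest p from each list, the 6 largest rises and falls in WT cells, and Dlx2, Neurog2, Sp8 and Sparcl1. Unnamed probes and Riken or predicted gene names were skipped in favour of the next gene. Of the list members the rule took, those printed were selected after their values were seen, mainly those that passed or belong to lists that did; the others enter the counts, the outlier check and the alternatives. Some list members that the rule took are not reported here. Xist, Ddx3y, Eif2s3y and Kdm5d were shown on each array after their values were seen. The labels say nothing of the sex of the mice.

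The fits were tested on simulated data with known changes in genes brighter than the median and array-to-array spread capped at its median, which makes recovery easier than in real data. For the proliferating comparison 90% of genes changed by 1 on the log2 scale and 98% of those changed by 2 were recovered, for the differentiating one 70% and 98%, for their difference 59% and 97%, for WT changes 36% and 93% and for KO changes 42% and 92%, with no wrong sign. Unchanged genes made up 8 of 102, 4 of 88, 11 of 167, 0 of 129 and 0 of 134 calls. By camera, a simulated list of 30 genes shifted by 0.5 in differentiating cells had an adjusted p of 2.56e-35 with the preset and 0.0714 with an estimated correlation. Of 100 random lists, 0 passed with either. The simulated noise was drawn independently for each gene, so this cannot show how often the preset calls unchanged lists of correlated genes. Estimated correlations of real lists called with the preset reached 0.143 for oligodendroglial and 0.238 for interferon response genes. Those of lists not called reached 0.162 for immediate early and stress genes and 0.631 for choroid plexus genes.

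Alternatives were other background, normalization, filter, probe and dye settings, each condition alone, eBayes with trend and robust prior, array weights, each array left out, a fold minimum of 1.5, the replicate number as a block, quantile normalization of channels and the authors' value table. Leaving out proliferating replicates 3 and 4 together was added after seeing the data. Slide was not used as a block, since each slide holds 1 condition.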

Results

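Gene expression was measured in neural stem cell cultures from the lateral ventricle walls of mice at postnatal day 14 to 21. Each of 6 arrays, with 2 colours, held RNA of wild-type (WT) cells in one dye and RNA of Dnmt3a-null (KO) cells in the other. On 4 arrays the cells were proliferating in growth factors. On 2 arrays they were differentiating, after 2 days of replating with mitogens and 3 days without. KO RNA carried Cy5 on proliferating replicates 1 and 3 and differentiating replicate 2, and Cy3 on the others. Between 52.3% and 59.1% of the gene spots were well above background per channel, and 18062 genes were tested. Log2 ratios are KO over WT, given as mean ± SD over the arrays (n = 4 for proliferating, n = 2 for differentiating cells), whose number limits the precision.

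Dnmt3a, the DNA methyltransferase that the KO cells lack, had less signal in KO than in WT cells on all 6 arrays. At the probe with the brightest signal (chromosome 12, 3825243 to 3826024, build mm7), its log2 ratio was -0.96 ± 0.22 in proliferating cells (adjusted p = 0.0219) and -1.38 ± 0.14 in differentiating cells (adjusted p = 0.0154). This was 1.94-fold and 2.61-fold lower, so signal remained in KO cells. A second probe (3826602 to 3826661) had mean log2 ratios of -0.61 and -0.40, and another (3830965 to 3831024) of -1.67 and -1.23. It is not known here which of these probes lie in the deleted part of Dnmt3a, and a probe outside it would check nothing.

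The comparison of KO with WT proliferating cells asks what loss of Dnmt3a changes in dividing stem cells. Of 28 oligodendroglial genes, 4 rose (adjusted p = 0.298 for the list with an estimated correlation), among them Sox10, a transcription factor that specifies this lineage, at 2.46 ± 0.49 (adjusted p = 0.0124) and Gpr17, a receptor of its precursor cells, at 2.35 ± 0.40 (adjusted p = 0.0129). Dhh, a hedgehog ligand, rose by 3.64 ± 1.06 (adjusted p = 0.0276), and Pou3f1, a POU domain transcription factor, by 2.25 ± 0.11 (adjusted p = 0.0111). Ramp1, a partner of the calcitonin receptor-like receptor, rose by 2.32 ± 0.29 (adjusted p = 0.0111). Eya1, a transcriptional coactivator, fell with a log2 ratio of -2.79 ± 0.85 (adjusted p = 0.0319). Sp8, a transcription factor of olfactory interneurons, fell with -1.70 ± 0.29 (adjusted p = 0.0163), and Dmrta2, a transcription factor of the dorsal forebrain, with -1.30 ± 0.41 (adjusted p = 0.0357). The KO signal was well above background on 3 of 4 arrays for Eya1 and Sp8 and on 2 for Dmrta2.

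Further genes that rose in proliferating KO cells were Xlr4b (3.36 ± 0.94) and Xlr3c (2.84 ± 0.62), both X-linked and lymphocyte-regulated, Vxn (2.64 ± 0.70), Arpp21 (2.31 ± 0.39), Pdlim3 (2.25 ± 0.62) and the nuclear receptor gene Nr2f2 (2.09 ± 0.42). WT signal was well above background on 3 of 4 arrays for Xlr4b, Vxn and Nr2f2, and on 2 for Xlr3c. Genes that fell included Arl4c (-1.18 ± 0.15), B3gnt5 (-1.18 ± 0.15, KO signal on 3 of 4 arrays), Nell2 (-1.18 ± 0.24), Naaa (-1.17 ± 0.74), Kremen1 (-1.17 ± 0.39), Pde2a (-1.16 ± 0.35), Slc14a2 (-1.11 ± 0.56), Lingo4 (-1.09 ± 0.29) and Obsl1 (-1.09 ± 0.26). All of these had the same sign on all 4 arrays. In total 172 genes passed limma's test, 111 higher and 61 lower in KO cells, 160 of them by at least 1.5-fold. The count was 30, 9 and 37 without proliferating replicate 2, 3 or 4 and 1 without either differentiating array, and 0 with the proliferating arrays fitted alone by limma (2275 at an unadjusted p under 0.05). With Agilent's processed signals it was 278, and without the filter on dim probes 101.

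The oligodendroglial genes that rose in proliferating KO cells were Sox10, Gpr17, Nkx2-2 and Bcas1, and 16 of the list rose when adjusted over the list alone. The list's median log2 ratio was 0.55 (camera adjusted p = 3e-10, and adjusted p = 0.298 with an estimated correlation), and 1.16 with Agilent's processed signals. It was 1.30 on replicate 4, which stood apart from the other proliferating arrays in both channels, against 0.31, 0.56 and 0.40 on replicates 1 to 3. Nkx2-2, a transcription factor of oligodendrocyte precursors, stood at 1.95 ± 0.70 (adjusted p = 0.0358), and Bcas1 at 2.07 ± 1.09 (adjusted p = 0.0462). Of 22 neurogenic transcription factors, Sp8 fell, and 1 rose and 6 fell when adjusted over the list alone. Their median was -0.22 (camera adjusted p = 0.0011, and adjusted p = 0.298 with an estimated correlation). Pax6 was at -1.50 ± 0.75 (adjusted p = 0.0503), Dlx2 at -1.70 ± 1.26 (adjusted p = 0.172; KO signal well above background on 3 of 4 arrays) and Neurog2, whose KO signal was not well above background, at least 1.53-fold lower (adjusted p = 0.0692). Dlx2, Neurog2, Sp8 and the astroglial gene Sparcl1 are known to have been studied in these cells, so their lists are not independent evidence. Sparcl1 was at 4.24 ± 2.18 (adjusted p = 0.0922), positive on all 4 arrays.

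Of 35 cell cycle genes in proliferating KO cells, none passed over all genes, 9 rose when adjusted over the list alone, and 32 were positive, with a median of 0.30 (camera adjusted p = 1.4e-09, and adjusted p = 0.298 with an estimated correlation). The median was 0.08, 0.26 and 0.25 on replicates 1 to 3 and 0.50 on replicate 4, whose cell cycle genes stood apart in both channels. Examples are Top2a at 0.36 (adjusted p = 0.0921) and Ccnd1 at 0.63 (adjusted p = 0.142). Among other lists, Cdkn1c, a cyclin-dependent kinase inhibitor that is also imprinted, rose by 0.98 ± 0.30 (adjusted p = 0.0321), and Cdkn1b, another such inhibitor, fell with -0.87 ± 0.50 (adjusted p = 0.0203). Of 23 Polycomb and H3K27 demethylase genes 2 fell, among them Cbx8 (-1.09 ± 0.59, adjusted p = 0.0460). Gap43, a growth cone protein, rose by 1.52 ± 0.53 (adjusted p = 0.0341), and Robo2, a receptor for Slit guidance cues, fell with -0.76 ± 0.07 (adjusted p = 0.0202; KO signal on 2 of 4 arrays).

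Sex-linked genes were unequal between the channels on proliferating replicates 3 and 4, the ones that hold most of the change in Dlx2 and Sparcl1. Xist, the RNA of the inactive X chromosome, had log2 signals of 12.69 and 13.34 in WT and 11.27 and 11.06 in KO RNA there, against 5.92 to 6.08, not well above background, in every other channel of the 6 arrays. Ddx3y, a Y-linked gene, had 6.05 and 5.89 in WT and 8.46 and 8.83 in KO RNA. Without both arrays, 238 genes passed in proliferating cells, 89 of them among the 172.

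**Figure D1:**
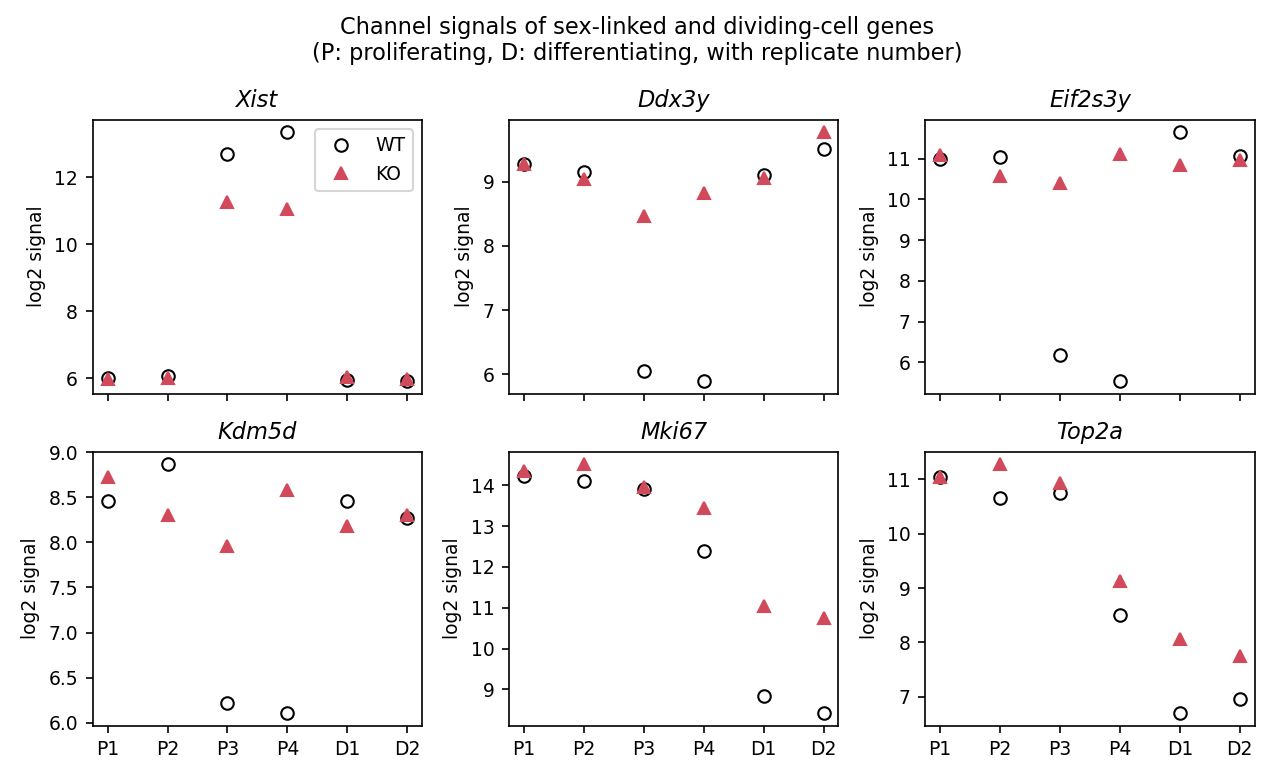
Normalized log2 signal of Xist, 3 Y-linked genes and the dividing-cell genes Mki67 and Top2a in the WT (circles) and KO (triangles) channel of each array, P for proliferating and D for differentiating with the replicate number. Xist is high in both channels of P3 and P4 only, and Ddx3y, Eif2s3y and Kdm5d are low in their WT channels.

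In differentiating cells, the comparison asks what loss of Dnmt3a changes once mitogens are withdrawn. Of 28 oligodendroglial genes, 10 rose in KO cells (adjusted p = 0.170 for the list with an estimated correlation), among them the myelin proteins Mag at 3.37 ± 0.55 (adjusted p = 0.0342) and Cldn11 at 3.36 ± 0.77 (adjusted p = 0.0197). The tetraspanin Tspan2 stood at 3.54 ± 0.15 (adjusted p = 0.0129). Aqp4, the water channel of astrocytes, rose by 2.91 ± 0.11 (adjusted p = 0.0077), and Mki67, a marker of dividing cells, by 2.28 ± 0.08 (adjusted p = 0.0153). Of 31 neuronal genes, 8 fell (adjusted p = 0.0745 for the list with an estimated correlation), among them Syt1, the calcium sensor of synaptic vesicles, with -2.50 ± 0.52 (adjusted p = 0.0127) and Tubb3, the tubulin of young neurons, with -1.56 ± 0.17 (adjusted p = 0.0147). Eya1 (-3.42 ± 0.46, adjusted p = 0.0271), Sp8 (-2.25 ± 0.28, adjusted p = 0.0147) and Dmrta2 (-1.71 ± 0.17, adjusted p = 0.0264) fell, as they did in proliferating cells.

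Other genes that rose in differentiating KO cells were Kcne1l (4.41 ± 0.42), Ramp1 (3.61 ± 0.13), the caveolin Cav1 (3.40 ± 0.09), S100a6 (3.38 ± 0.58), Cidea (3.28 ± 0.59), a protein of lipid droplets, Gas6 (3.21 ± 0.11), a receptor tyrosine kinase ligand, Naprt (3.18 ± 0.20), Pdlim2 (3.16 ± 0.13) and the growth factor midkine, Mdk (3.14 ± 0.32). Other genes that fell were the receptor Kit (-2.67 ± 0.18), Celf3 (-2.52 ± 0.02), Nxph1 (-2.01 ± 0.38), Add2 (-1.83 ± 0.10), Megf11 (-1.82 ± 0.70) and Slc14a2 (-1.82 ± 0.60). Gpr149 and Gjd2, the latter the connexin of neuronal gap junctions, were not well above background in KO cells and were at least 5.04-fold (adjusted p = 0.0077) and at least 4.84-fold lower (adjusted p = 0.0145). In total 557 genes passed limma's test, 394 higher and 163 lower in KO cells, 530 of them by at least 1.5-fold. With either differentiating array left out, limma called 0 genes (1206 without replicate 1 and 1750 without replicate 2 at an unadjusted p under 0.05). The count was 285 with median centring, 1711 with array weights, 1586 with the differentiating arrays fitted alone and 1045 without proliferating replicates 3 and 4.

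**Figure D2:**
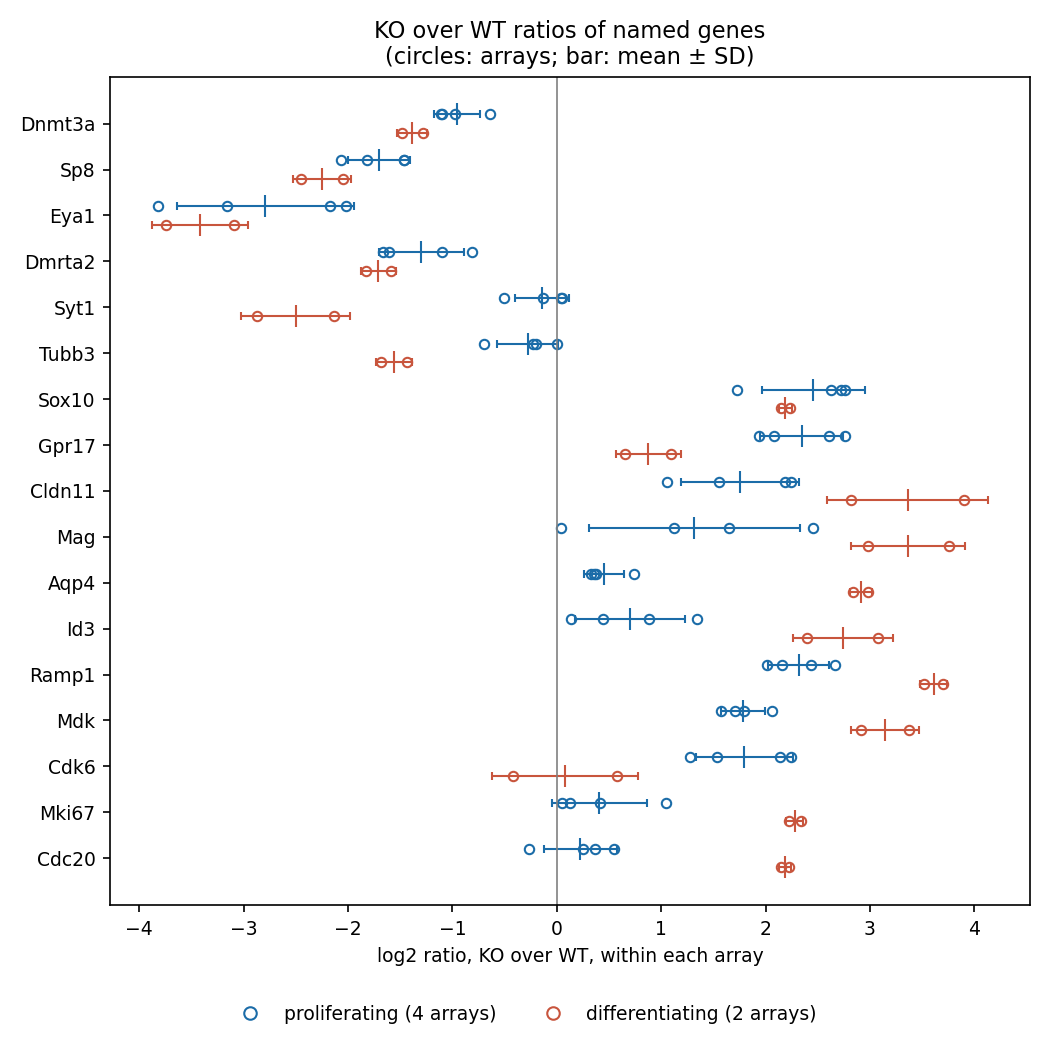
Log2 KO over WT ratio within each array for 17 named genes, with circles for arrays and bars for mean ± SD, in proliferating (n = 4) and differentiating (n = 2) cells. Dnmt3a, Sp8, Eya1 and Dmrta2 lie below 0 on all 6 arrays, and Syt1 and Tubb3 have means of -2.50 and -1.56 in differentiating cells.

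Of 35 cell cycle genes, 19 rose in differentiating KO cells and none fell, and 27 rose when adjusted over the list alone. The list's median log2 ratio was 0.86 (camera adjusted p = 3.6e-21, and adjusted p = 0.0745 with an estimated correlation), and 1.53 with Agilent's processed signals. Cdc20, an activator of the anaphase-promoting complex, rose by 2.19 ± 0.06 (adjusted p = 0.0134), Kif20a by 1.83 ± 0.06 (adjusted p = 0.0141), Aurka, a mitotic kinase, by 1.42 ± 0.16 (adjusted p = 0.0129) and Top2a by 1.07 ± 0.41 (adjusted p = 0.0147). Of the oligodendroglial genes, 19 rose and 1 fell when adjusted over the list alone. Their median was 1.49 (camera adjusted p = 5.6e-13, and adjusted p = 0.170 with an estimated correlation). Cnp rose by 2.20 ± 0.05 (adjusted p = 0.0108), Sox10 by 2.19 ± 0.06 (adjusted p = 0.0170), Mobp by 3.06 ± 0.07 (adjusted p = 0.0129) and Mal by 2.06 ± 0.25 (adjusted p = 0.0108). WT signal of Mobp and Mal was well above background on 1 of 2 arrays.

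Of the neuronal differentiation and synapse genes, 16 fell in differentiating KO cells when adjusted over the list alone. The list's median was -0.44 (camera adjusted p = 1.2e-10, and adjusted p = 0.0745 with an estimated correlation), with 29 members negative, and -0.784 with Agilent's processed signals. Map2, a dendritic microtubule protein, fell with -0.95 ± 0.13 (adjusted p = 0.0159), and Cntn2, an axonal adhesion protein not well above background in KO cells, was at least 1.90-fold lower (adjusted p = 0.0156). Of 22 neurogenic transcription factors, 4 fell, and 1 rose and 12 fell when adjusted over the list alone. Their median was -0.86 (camera adjusted p = 2.1e-07, and adjusted p = 0.107 with an estimated correlation). These were Sp8, Myt1l (-1.25 ± 0.20, adjusted p = 0.0147; KO signal on 1 of 2 arrays), Neurod2 (-0.60 ± 0.02, adjusted p = 0.0338) and Neurog2, not well above background in KO cells and at least 1.81-fold lower (adjusted p = 0.0449). Dlx2 and Sparcl1 did not pass (adjusted p = 0.271 and 0.859), so no minimum change is established for either. The mean of Dlx2 was at least 3.22-fold lower, its KO signal not well above background. That of Sparcl1, saturated in KO cells, was at least 1.53-fold higher.

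Of 31 astroglial genes, 4 rose in differentiating KO cells, and 7 rose and 5 fell when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0902; 0.0204 to 0.0443 under 6 alternatives, leaving out differentiating replicate 2 or proliferating replicate 1 or 3 among them). They were Aqp4, Id3 (2.74 ± 0.48, adjusted p = 0.0077), the connexin Gjb6 (1.23 ± 0.25, adjusted p = 0.0421) and Clu (2.06 ± 0.18, adjusted p = 0.0483). Of 14 ependymal and cilia genes, 4 rose and 1 fell, with a median of 0.46 (camera adjusted p = 0.0075, 0.227 without differentiating replicate 2, and adjusted p = 0.253 with an estimated correlation). Those that rose include Mlf1 (1.44 ± 0.61, adjusted p = 0.0215) and the axonemal dynein Dnahc9 (0.92 ± 0.36, adjusted p = 0.0195), and Cd24a fell (-1.07 ± 0.56, adjusted p = 0.0448). Of 22 interferon response genes, Gbp2 rose (1.49 ± 0.53, adjusted p = 0.0368), and the median was 0.23 (0.368 with Agilent's processed signals; camera adjusted p = 5.5e-04, 0.483 without differentiating replicate 1, and adjusted p = 0.447 with an estimated correlation). Of 23 Polycomb and H3K27 demethylase genes, Cbx8 fell (-1.40 ± 0.42, adjusted p = 0.0345), and 4 fell when adjusted over the list alone. Their median was -0.10 (-0.165 with Agilent's processed signals; camera adjusted p = 0.0238, 0.0809 with processed signals, 0.0509 with no dye term, 0.0544 and 0.0617 without differentiating replicate 1 or 2, and adjusted p = 0.253 with an estimated correlation).

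**Figure D3:**
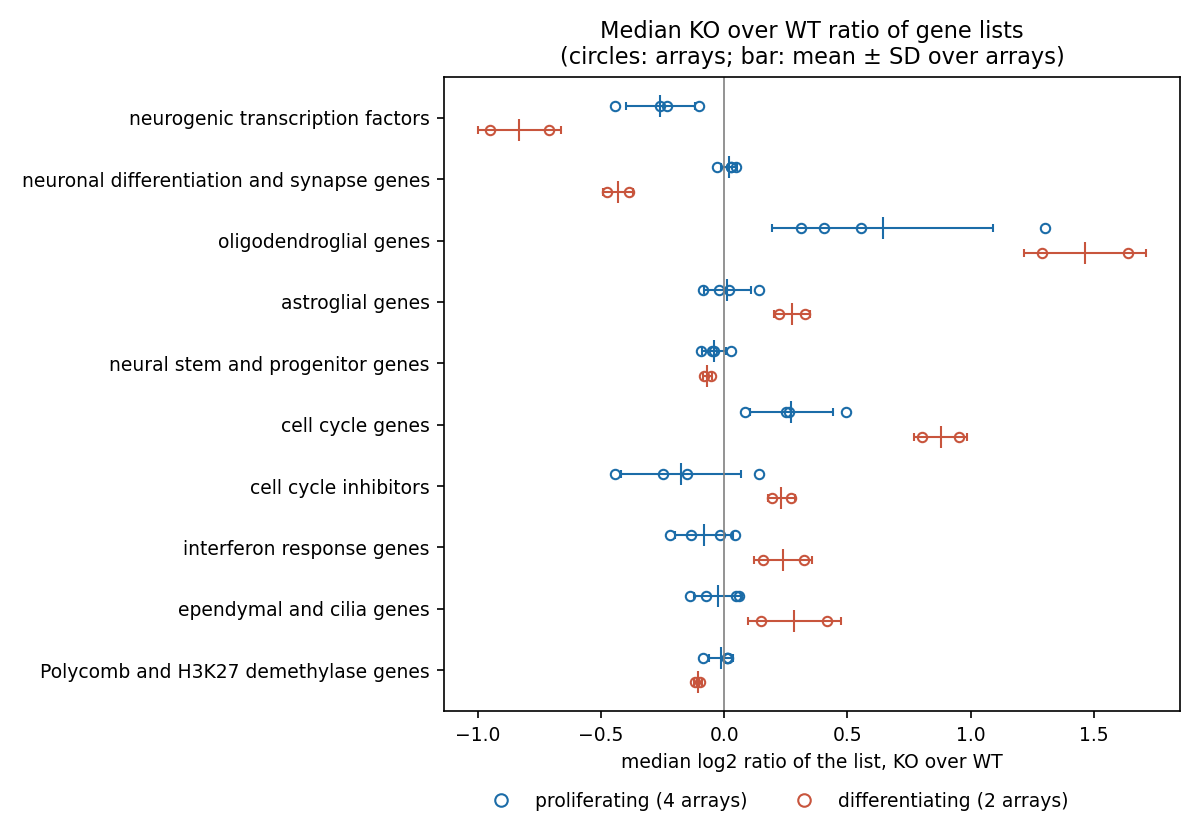
Median log2 KO over WT ratio of 10 gene lists on each array, with circles for arrays and bars for mean ± SD over arrays, in proliferating (n = 4) and differentiating (n = 2) cells. The oligodendroglial median lies between 0.31 and 1.30 on proliferating arrays and at 1.64 and 1.29 on differentiating ones, and the neuronal median at -0.39 and -0.47 on the latter.

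Genes that regulate growth and DNA methylation were among the single members that changed in differentiating KO cells. Uhrf1, which brings the maintenance methyltransferase to replicated DNA, rose by 1.32 ± 0.01 (adjusted p = 0.0285). Cdkn1c rose by 1.42 ± 0.06 (adjusted p = 0.0206) and Gadd45b, a stress-induced inhibitor, by 2.09 ± 0.81 (adjusted p = 0.0320), and Cdkn1b fell with -0.69 ± 0.63 (adjusted p = 0.0477). Of 28 stem and progenitor genes 1 fell and 2 rose, Id1 (3.07 ± 0.51, adjusted p = 0.0330) and Prom1 (1.93 ± 0.50, adjusted p = 0.0220). Of 28 patterning genes 1 fell and 2 rose, the secreted signals Bmp4 (2.65 ± 0.06, adjusted p = 0.0334) and Wnt7b (0.97 ± 0.17, adjusted p = 0.0170). The imprinted gene Ddc rose (2.55 ± 0.28, adjusted p = 0.0325), and the germline gene Rhox2a fell (-1.19 ± 0.06, adjusted p = 0.0154). Thy1 (2.53 ± 0.04, adjusted p = 0.0258), Folr1 (1.44 ± 0.27, adjusted p = 0.0133) and Drc1 rose as well (1.23 ± 0.21, adjusted p = 0.0313).

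Both conditions were set against each other to see whether the KO effect recurs after mitogen withdrawal. Ramp1, Sox10, Eya1, Sp8 and Dmrta2 passed in both, with the same sign. Of the 172 genes called in proliferating cells, 157 had the same sign in differentiating cells, 91.3% (95% exact interval 86.0 to 95.0%), against 61.0% of all tested genes. The interval treats genes as independent and does not measure the spread over cultures. Of the 557 called in differentiating cells, 473 (84.9%) had the same sign in proliferating cells. There were 60 genes called higher in both, 22 called lower in both and 2 called in opposite directions. Independent calls would give 2.42, 0.55 and 2.33. The calls are not independent, since both conditions share 1 estimate of each gene's spread and a dye term, so those figures do not measure chance. Across genes, which are not independent replicates, the ratios of both conditions correlated with Pearson's r = 0.463 and Spearman's rho = 0.319.

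**Figure D4:**
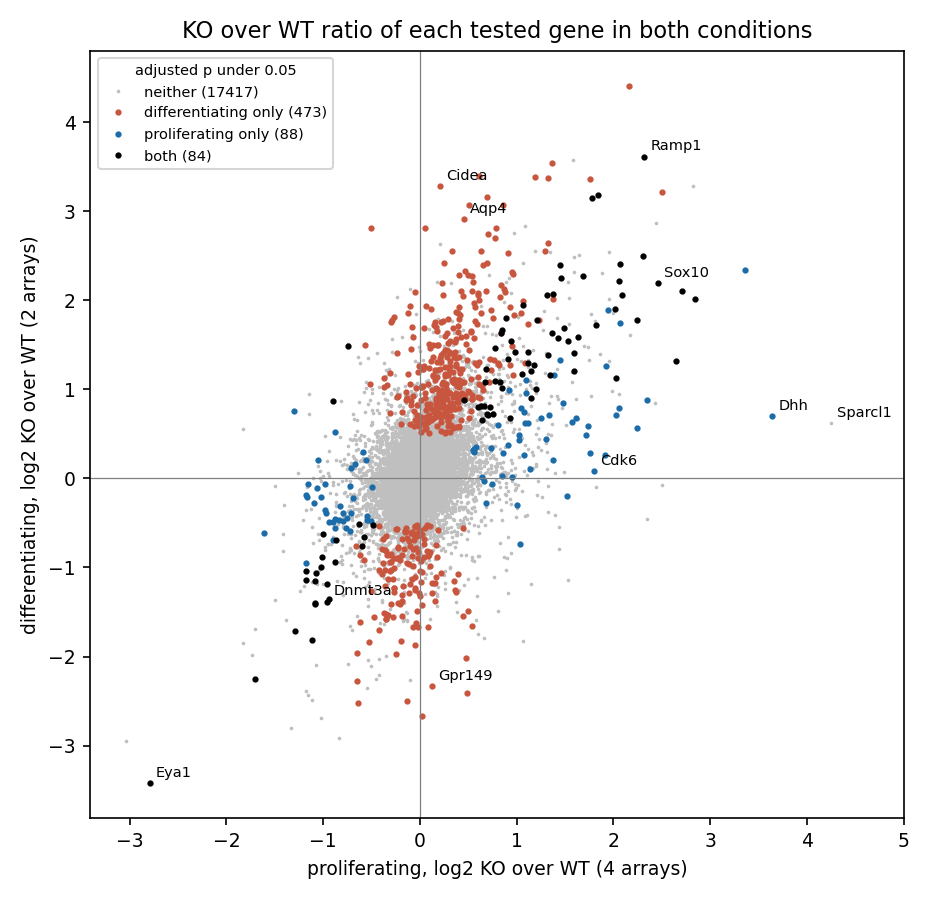
Log2 KO over WT ratio of each tested gene in proliferating (horizontal, 4 arrays) and differentiating cells (vertical, 2 arrays), coloured by the condition in which its adjusted p is under 0.05. The 84 genes called in both lie mostly along the diagonal, with Ramp1 and Sox10 at the upper right and Eya1 at the lower left.

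The difference between the KO effects, differentiating minus proliferating, passed for 9 genes, 6 positive and 3 negative. Aqp4 had the larger KO rise in differentiating cells (difference 2.46, adjusted p = 0.0395), as did Cidea (3.07, adjusted p = 0.0443) and Tspan17 (1.66, adjusted p = 0.0395). Rgs16, a regulator of G protein signalling, turned from -0.74 (adjusted p = 0.0335) to 1.49 (adjusted p = 0.0140), a difference of 2.23 (adjusted p = 0.0395). Cdk6, a kinase of the G1 phase, rose by 1.80 ± 0.47 in proliferating cells and stood at 0.08 ± 0.70 (adjusted p = 0.792) in differentiating ones, a difference of -1.72 (adjusted p = 0.0443). Gpr149, not well above background in differentiating KO cells and measured in 1 WT and 2 KO channels of proliferating cells, had a difference of -2.45 (adjusted p = 0.0395). Bbox1, not well above background in proliferating cells, had one of 1.78 (adjusted p = 0.0443). Values that did not pass include Syt1 at -2.37 (adjusted p = 0.0557), Bcl11b at -1.99 (adjusted p = 0.0557) and Myt1l at -1.61 (adjusted p = 0.0507). Myt1l was measured in 1 of 4 proliferating KO channels and in no WT one, so its value is not the size of a measured difference. The difference was -0.55 for Sp8 (adjusted p = 0.447) and -0.43 for Dnmt3a (adjusted p = 0.384). With the mean of its probes, the log2 difference of Dnmt3a was 0.076 (adjusted p = 0.836). The difference did not pass for Dlx2, Neurog2 or Sparcl1 (adjusted p = 0.998, 0.668 and 0.389). Their values are not sizes of a measured change, since their KO signals were not well above background or, for Sparcl1, saturated in differentiating cells.

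Among lists, the KO effect on cell cycle genes was larger in differentiating cells, by a median of 0.57 (1.21 with Agilent's processed signals; camera adjusted p = 6.5e-15, and adjusted p = 0.123 with an estimated correlation), and 18 members passed when adjusted over the list alone. That on neuronal genes was more negative, by -0.88 (-1.32 with Agilent's processed signals; camera adjusted p = 2.9e-11, and adjusted p = 0.123 with an estimated correlation), with 19 members alone. Examples are Cdc20 at 1.96 (adjusted p = 0.0886), Aurka at 1.11 (adjusted p = 0.0886) and Syt1, none of which passed over all genes. With any 1 array left out limma called 0 genes (852 to 2585 at an unadjusted p under 0.05). The count was also 0 with median centring, without the filter on dim probes and with the mean of a gene's probes (1582, 2865 and 2109 at an unadjusted p under 0.05), 72 with Agilent's processed signals and 124 with array weights.

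After mitogen withdrawal, most cell cycle genes fell in WT cells, and 11 of 31 neuronal genes rose. Mki67 fell with a log2 change of -5.08 in WT and -3.21 in KO cells (adjusted p = 0.0037 in KO), and Pimreg, Pbk and Cdca3 with -5.00, -4.85 and -4.81 in WT cells. Of 35 cell cycle genes, 30 fell in WT (median -3.35) and 23 in KO cells (median -2.55), and 35 in each when adjusted over the list alone. Dcx, a microtubule protein of migrating neuroblasts, rose by 5.15 in WT cells (adjusted p = 0.0021), Cntnap2, a neuronal adhesion protein measured in 1 of 4 proliferating WT channels, by 4.68 (adjusted p = 5.5e-04), and Eva1a, Cldn10, Phactr3 and Padi2 by 4.24, 4.24, 4.23 and 4.22. Proliferating WT signal was well above background on 3 of 4 arrays for Dcx, Eva1a and Padi2 and on 2 for Cldn10 and Syt1. Car3 and Angpt2 fell in WT cells to a signal not well above background on either array, for which no fold is given. Neuronal genes had a median of 0.81 in WT cells, with Syt1 at 2.92, and in KO cells 2 rose and 1 fell (median 0.23), with Elavl3 at 2.20 and Gap43 at -2.50.

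Of 28 oligodendroglial genes, 3 rose and 1 fell in WT cells (median 0.82), and 10 rose and 1 fell in KO cells (median 1.5). Of 31 astroglial genes, 7 rose and 1 fell in WT (median 0.98) and 9 rose and 1 fell in KO cells (median 1.00), and Aldoc rose by 1.47 and 1.51. Nes, an intermediate filament of neural progenitors, fell with -2.19 in WT and -3.02 in KO cells, Uhrf1 with -3.80 and -2.80, and Ezh2, the Polycomb methyltransferase, with -1.05 and -1.23. In all, 2526 genes passed in WT (1337 higher, 1189 lower) and 2604 in KO cells (1387 higher, 1217 lower). All proliferating arrays lie on one slide and both differentiating arrays on another, so slide and condition cannot be told apart in these changes or in the difference between KO effects. With 1 array left out, the counts ranged from 104 (without differentiating replicate 1) to 3822 (without proliferating replicate 4) in WT and from 63 to 4720, without the same arrays, in KO cells, and they were 1066 and 1365 without proliferating replicates 3 and 4 and 5862 and 6321 with the replicate number as a block. Replicate 4 stood apart among proliferating arrays, its cell cycle genes at a median of -0.57 in WT and -0.25 in KO RNA relative to the mean of all channels, against 1.18 to 1.62 on the other proliferating arrays and -2.66 to -1.32 on the differentiating ones.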

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

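The tests of the normalization and of cell composition below were chosen only after the result was seen.

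The cell cycle list was higher in KO than in WT cells in both conditions by camera with the preset correlation, and the KO effect was larger in differentiating cells, by a median of 0.567, calls that end with an estimated correlation (adjusted p = 0.298 in proliferating cells, adjusted p = 0.0745 in differentiating cells and adjusted p = 0.123 for the difference). The choice among the normalization and background settings run does not account for it as a whole, since the list's median in differentiating cells was 0.849 to 1.53. The difference ranged from 0.422 with median centring to 1.21 with Agilent's processed signals. All of these settings centred the ratios, with medians of all genes of -0.0507 to -0.0072 in differentiating cells. A normalization without such centring was not tested. A smaller share of neurons alone would raise all other cell types alike. The cell cycle median lay 0.882 above that of 28 stem and progenitor genes. Its bootstrap 95% interval, 0.717 to 1.28, is over genes and not over arrays. On differentiating replicates 1 and 2 the cell cycle medians were 0.954 and 0.802, and the stem and progenitor medians -0.0543 and -0.0811. A uniform rise is thus excluded as the whole cause. Oligodendroglial genes had a median of 1.49 and astroglial genes of 0.24, and a change in the shares of the other cell types was not tested. KO cells that leave the cell cycle later or less often after mitogen withdrawal are a candidate explanation, and no test here separates it from cultures that differed in density or from the slide, which cannot be told apart from condition.

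In 7 other lists the KO effect also differed between conditions by camera's test with the preset correlation. The median difference was -0.877 for neuronal genes (adjusted p = 0.123 with an estimated correlation), with Syt1 at -2.37 (adjusted p = 0.0557). It was 0.414 for oligodendroglial genes (camera adjusted p = 0.0010, 0.152 with the filter on all arrays, 0.107 without differentiating replicate 2, and adjusted p = 0.334 with an estimated correlation), with Mal at 1.82 (adjusted p = 0.0557) and Cnp at 1.66 (adjusted p = 0.0864). For neurogenic transcription factors it was -0.29 (-0.627 with processed signals; adjusted p = 0.0061, 0.177 with the filter on all arrays, 0.0835 without differentiating replicate 1, and adjusted p = 0.257 with an estimated correlation), with Neurod2 at -0.52 (adjusted p = 0.166). Astroglial genes had 0.261 (adjusted p = 0.0226, 0.0776 with processed signals, 0.0678 with the filter on all arrays, 0.102 without proliferating replicate 2, 0.303 without differentiating replicate 1, and adjusted p = 0.257 with an estimated correlation), with Id3 at 2.04 (adjusted p = 0.0557). Cell cycle inhibitors had 0.421 (adjusted p = 0.0063, 0.066 without differentiating replicate 1, 0.0756 without proliferating replicates 3 and 4, and adjusted p = 0.257 with an estimated correlation), with Gadd45b at 2.14 (adjusted p = 0.130) and Cdkn2c at 0.56 (adjusted p = 0.250). Interferon response genes had 0.349 (0.533 with processed signals; adjusted p = 3.2e-05, 0.087 without differentiating replicate 1, and adjusted p = 0.320 with an estimated correlation), with Gbp2 at 2.07 (adjusted p = 0.0955) and Gbp3 at 1.26 (adjusted p = 0.193). Ependymal and cilia genes had 0.481 (adjusted p = 0.0052, 0.271 without differentiating replicate 2, and adjusted p = 0.257 with an estimated correlation), with Dnahc9 at 0.99 (adjusted p = 0.0886) and Dnah11, not well above background in proliferating cells, at 0.55 (adjusted p = 0.157).

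The difference between KO effects also passed for 9 single genes. Those that the rule for named genes took were Cidea (3.07), Gpr149 (-2.45), Aqp4 (2.46), Rgs16 (2.23), Bbox1 (1.78), Tspan17 (1.66) and Cdk6 (-1.72). The value of Gpr149, not well above background in differentiating KO cells, is not the size of a measured difference. Nor are those of Bbox1 and, in the lists above, Dnah11, both not well above background in proliferating cells.

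Of 194 named genes, 9 had 1 proliferating array far from the other 3. On replicate 4 these log2 KO over WT ratios were 1.45 for Nr2f2, 2.23 for Pdlim2, -0.636 for Bmi1, 0.495 for Kif11 and -0.428 for Ifit3. On replicate 2 they were 1.73 for Sox10 and 0.742 for Aqp4, and on replicate 1 0.139 for Bcl11b and 0.531 for Cdkn1c. Chance alone singles out about 1 gene in 20.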

How the results depend on the processing

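Results without proliferating replicates 3 and 4 together were computed only after the data had been seen. Every gene named in the text as passing for KO against WT in either condition kept its direction under each alternative run. The calls themselves rest on few arrays and on the shared estimate of the spread, and signals not well above background limit what was measured. Where a value moved, the cause was not tested, except that leaving out an array or fitting a condition alone leaves fewer arrays for the spread.

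In proliferating cells 172 genes passed as reported. The count was 278 with Agilent's processed signals (184 higher, 94 lower), 270 with the authors' value table, 101 without the filter on dim probes and 0 with each condition alone (limma; 2275 at an unadjusted p under 0.05). With 1 array left out it ranged from 1 to 176. The higher share of 64.5% of calls was 77.8% with median centring (105 higher, 30 lower) and 74.7% with no dye term (177 higher, 60 lower). The share with the same sign in differentiating cells was 85.6% with processed signals, 83.3% with the value table, and 82.95% to 100% with 1 array left out.

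In differentiating cells the count of 557 became 285 with median centring, 1586 with each condition alone, 1711 with array weights, 1045 without proliferating replicates 3 and 4 (492 of them among the 557), and 0 to 539 with 1 array left out (limma; 1206 and 1750 at an unadjusted p under 0.05 where it was 0). For the difference between KO effects, 9 genes became 72 with processed signals, 81 with the value table, 24 with no dye term, 16 with trend and robust prior, 124 with array weights, 4 with the filter on all arrays and 29 without proliferating replicates 3 and 4. It was 0 by limma with median centring, no filter, the mean of all probes and any 1 array left out (852 to 2865 at an unadjusted p under 0.05). Within WT cells 2526 genes became 1066 without proliferating replicates 3 and 4 and 104 to 3822 with 1 array left out, and within KO cells 2604 became 1365 and 63 to 4720.

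Lists called were 3 in proliferating cells (3 to 6 with 1 array left out), 7 in differentiating cells and 8 for the difference (5 to 8 with 1 array left out, 5 with the filter on all arrays). List medians moved by over 1.5 times only with processed signals and the value table among the normalization, background and dye settings, for the lists called. In differentiating cells the cell cycle median was 1.53, the neuronal -0.784, the interferon 0.368 and the Polycomb -0.165 with both, in proliferating cells the oligodendroglial 1.16 and 1.17, and for the difference the cell cycle 1.21, the neuronal -1.32, the neurogenic -0.627 and the interferon 0.533. With an estimated correlation camera called 0 in each, against 3, 4 and 2 at an unadjusted p under 0.05.

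The replicate number was used as a block for results that span both conditions. Arrays of both conditions share only the numbers 1 and 2, and the labels tie no number to a mouse, litter or day, so they share only a number. The ratio deviations of same-numbered arrays correlated across genes at -0.369 and -0.288, which decides nothing, since centring makes the 2 differentiating arrays exact opposites and same-numbered arrays carry KO RNA in opposite dyes. In the fit of KO over WT ratios the block took the place of the dye term and gave proliferating replicates 3 and 4 a coefficient each. Those arrays thus had no part in the difference, whose values equal those without both (Dlx2 -0.95 in each). The block is therefore not a separate check of its size. With the replicate block, 0 genes passed limma's test for the difference between KO effects (1042 at an unadjusted p under 0.05). By camera 7 lists were called (cell cycle inhibitors no longer, adjusted p = 0.0547), and 5862 and 6321 genes passed within WT and KO cells.

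Of single genes, none that passed on either side turned direction. Those that turned without passing were, as log2 KO over WT in proliferating cells, Aqp1 (-0.033 with processed signals, -0.0077 with median centring, -0.13 with the value table), C1qb and Cd14 (0.021 and 0.13 without proliferating replicates 3 and 4) and Cd68 (-0.11 to 0.025 with 1 array left out). In differentiating cells they were Kdm6a (-0.019 with processed signals and the value table, -0.0051 with median centring), Uhrf2 (0.040 with the mean of all probes) and, with 1 array left out, C1qb (-0.36 to 0.095), Cd68 (-0.29 to 0.38), Eif2s3y (-1.0 to 0.082) and Pdgfrb (-1.17 to 0.048). For the difference they were Dlx2, not well above background in differentiating KO cells (-0.052 without background correction, -1.01 with processed signals and the value table, -0.0026 with median centring, -0.95 with the replicate block and without proliferating replicates 3 and 4, -0.76 to 0.79 with 1 array left out) and Dnmt3a (0.076 with the mean of all probes). Calml4 (-0.13), Otx2 (-0.19) and Fcer1g (4.6e-05) turned with the replicate block and without proliferating replicates 3 and 4. These settings give the same estimate of the difference and are not separate checks. With 1 array left out, C1qb (-0.32 to 0.13), Cd68 (-0.26 to 0.42), Hoxb6 (-0.89 to 0.0096) and Pdgfrb (-1.21 to 0.0031) turned. Xist within KO cells was 0.45 with the replicate block, and Cd68 within WT cells -0.10 to 0.34 with 1 array left out.

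Of lists, 1 that turned passed on a side, the immediate early and stress genes in differentiating cells, with an adjusted p of 0.0219 upon leaving out replicate 2 and 7.51e-05 in the other direction without replicate 1 (up to 0.791 with 1 array left out), and 2.41e-06 to 0.655 for the difference. The others passed on neither side and are given by camera's adjusted p. In proliferating cells these were neuronal genes (0.913 with processed signals, 0.847 with no filter, 0.891 with the filter on all arrays, 0.673 to 0.925 with 1 array left out), astroglial genes (0.786 with processed signals, 0.969 without proliferating replicates 3 and 4, 0.844 to 0.988 with 1 array left out), germline genes (0.838 with the filter on all arrays, 0.466 to 0.922), patterning genes (0.614 with median centring, 0.686 to 0.922), ependymal genes (0.501 with the filter on all arrays, 0.673 to 0.995) and sex-linked genes (0.673 to 0.988). In differentiating cells they were germline genes (0.94 with processed signals, 0.922 with the filter on all arrays), Hox genes (0.633 with that filter), patterning genes (0.993 with processed signals, 0.954 with median centring, 0.895 with no filter, 0.922 with the filter on all arrays, 0.791 to 0.949), stem and progenitor genes (0.451 to 0.909) and microglial genes (0.611 to 0.944).

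For the difference, the lists that turned were DNA methylation genes (0.72 with the mean of all probes, 0.944 with no dye term, 0.956 with the replicate block, 0.816 to 0.96 with 1 array left out), germline genes (0.815 with the filter on all arrays) and patterning genes (0.991 without background correction, 0.491 with median centring, 0.962 with no filter, 0.801 with the filter on all arrays, 0.944 with no dye term, 0.892 with array weights, 0.673 to 0.969). Further ones were endothelial genes (0.711 with median centring, 0.79 with no filter, 0.619 with the filter on all arrays, 0.861 with the replicate block, 0.769 without proliferating replicates 3 and 4, 0.796 to 0.967), choroid plexus genes (0.647 with the block, 0.44 without both of those arrays) and sex-linked genes (0.858 with the filter on all arrays, 0.859 with the mean of all probes, 0.995 without both of those arrays, 0.795 to 0.97). With 1 array left out, stem and progenitor (0.0767 to 0.969), imprinted (0.459 to 0.964) and Hox genes (0.585 to 0.963) turned as well.

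Array weights were not run for changes within WT or KO cells, since the separate-channel fit takes none, and camera takes no robust prior. Slide as a block was not run, since each slide holds 1 condition.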

Other observations

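The tests of sex and of proliferating replicate 4 below were chosen only after these results were seen.

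The germline, imprinted, Hox and patterning genes, groups in which DNA methylation is known to silence members, passed as lists in neither condition as reported. Of 13 measured germline genes (37 on the list), none passed as higher over all genes in either condition. Their median log2 ratio was -0.05 in proliferating (camera adjusted p = 0.709) and 0.04 in differentiating cells (adjusted p = 0.840). Of 30 imprinted genes, 1 rose in proliferating (median 0.11, adjusted p = 0.167; 0.048 without the filter on dim probes and 0.0265 without proliferating replicate 3) and 2 rose in differentiating cells (median 0.01, adjusted p = 0.569). The 12 Hox genes had medians of 0.04 (adjusted p = 0.167) and 0.01 (adjusted p = 0.539), and the 28 patterning genes -0.01 (adjusted p = 0.831) and -0.04 (adjusted p = 0.873). When adjusted over the list alone, 2 germline, 5 imprinted, 3 Hox and 5 patterning genes rose in proliferating cells, and 5 patterning genes fell. In differentiating cells 4 imprinted, 2 Hox and 3 patterning genes rose, and 1 germline, 2 imprinted and 3 patterning genes fell. Of 16 DNA methylation and demethylation genes, Dnmt3a fell in both conditions and Uhrf1 rose in differentiating cells, with medians of -0.01 (adjusted p = 0.536) and -0.10 (adjusted p = 0.563). The 23 Polycomb genes had a median of -0.03 in proliferating cells (adjusted p = 0.382), the 22 interferon response genes -0.04 (adjusted p = 0.195) and the 13 genes of the Dnmt3a neighbour list, among them Hadha, Hadhb and Drc1 on chromosome 5, 0.00 (adjusted p = 0.709; 0.05 and adjusted p = 0.303 in differentiating cells).

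Markers of other cell types passed as lists in neither condition as reported, apart from the ependymal genes in differentiating cells. The medians in proliferating and differentiating KO over WT were -0.03 and -0.01 for 4 measured microglial genes (adjusted p = 0.669 and 0.847), 0.12 and 0.31 for 11 endothelial and mural genes (0.120 and 0.303), 0.12 and 0.37 for 9 fibroblast and meningeal genes (0.167 and 0.0877) and 0.15 and 0.16 for 6 choroid plexus genes (0.195 and 0.303). The fibroblast list passed in differentiating cells under 7 alternatives, with adjusted p of 0.0187 with processed signals and with median centring, 0.00694 without the filter on dim probes, 0.0142 with the filter on all arrays, 0.045 with no dye term, and 0.0201 and 0.048 without proliferating replicate 2 or differentiating replicate 1. In proliferating cells the endothelial list passed with processed signals (0.0492) and without replicate 2 (0.0369), and the choroid plexus list without replicates 3 and 4 (0.00117). Neuronal, astroglial and ependymal genes had -0.04, -0.01 and -0.07 in proliferating cells (0.832, 0.846 and 0.846). Stem and progenitor genes had -0.09 and -0.02 (0.190 and 0.869), cell cycle inhibitors -0.12 and 0.24 (0.167 and 0.303), both lists passing in proliferating cells without replicate 2 (0.046 and 0.0369), and sex-linked genes -0.18 and 0.00 (0.712 and 0.873). Immediate early and stress genes had 0.06 and 0.02 (0.536 and 0.633), the latter over differentiating arrays at 0.28 and -0.34, and the list passed as lower without differentiating replicate 1 (7.51e-05) and as higher without replicate 2 (0.0219). The sign of the median, the mean or the test differed within the neuronal, astroglial, germline, patterning, ependymal, sex-linked and Dnmt3a neighbour lists in proliferating cells, within the stem, germline, patterning, immediate early, microglial and sex-linked lists in differentiating cells, and within the DNA methylation, imprinted, Hox, patterning and sex-linked lists for the difference. After mitogen withdrawal, Pdgfrb rose by 4.08 in WT and 3.48 in KO cells, Nkx6-2, a homeodomain factor of oligodendrocytes, by 3.81 in KO cells and Gbp2 by 2.93 in KO cells.

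On proliferating replicates 3 and 4 the WT RNA held Xist with little signal of the Y-linked genes, and the KO RNA held both Xist and Y-linked signal (Eif2s3y 10.39 and 11.10, against 6.17 and 5.54 in WT RNA), which is consistent with female WT cells and KO cells of both sexes. A sex difference is excluded as the whole cause of the proliferating calls. Of these, 91.3% kept their sign in differentiating cells, against 61.0% of all genes, and Xist was at 5.92 to 6.03 there in both genotypes. Both shares are over genes, which are not independent replicates. Part of the differences on these arrays, among them those of Sparcl1 (6.89 and 5.16, against 2.38 and 2.53 on replicates 1 and 2) and Dlx2 (-2.41 and -2.94, against -0.08 and -1.39), may come from sex or from other differences between the mice. The design names no sex, and no biological explanation of it was tested.

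On the first principal component (53.6% of the variance), proliferating replicate 4 lay between the conditions, at 7.95 in WT and 1.85 in KO RNA. The other proliferating arrays lay at -55.7 to -32.8 and the differentiating ones at 58.9 to 68.8. On the second component (14.5%) replicate 4 lay at -62.8 in WT and -36.4 in KO RNA. All other channels lay at -5.49 to 31.0 there, so replicate 4 also stood apart from both conditions. Array noise unrelated to the cells is excluded as the whole cause, since 78.8% of 2604 genes in WT and 80.2% of 2516 in KO RNA that differ between differentiating cells and replicate 1 shifted the same way in replicate 4. Replicate 4 covered a median of 0.395 (WT) and 0.461 (KO) of the distance to the differentiating arrays. Those arrays lie on another slide, so part of that distance may come from the slide. A culture as far along as theirs could thus also fall short of the whole distance, and the shares do not exclude it. Nor can they exclude a culture with a shorter mitogen withdrawal or a mixture of RNA, which could give such shares. Cultures of both genotypes that had partly left the cell cycle when harvested are a candidate explanation, which no test here addressed.

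The 4 proliferating arrays allow 8 assignments of genotype to the dyes, too few for a share under 0.05. The real one gave 172 genes, and the highest of the others, which include the one that follows the dye, gave 0 by limma. That makes 1 assignment of 8 with as many genes.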
